A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

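Total RNA was prepared, per the labels, from log-growing cells of 4 mutant strains and of wild type in rich medium at 30 °C, depleted of ribosomal RNA, and reverse transcribed with indirect labelling, the mutant in Cy5 and wild type in Cy3. Each genotype had 1 array, mutant and wild type always had the same dyes, and no pooling was stated. The arrays carried 43993 probes of 60 nt, of which 40078 matched the genome once and 3915 several times per the deposited probe annotation. Most probes (41974) lay on chromosome 2, spaced every 50 bp over both strands from 1000011 to 3049820 and from 4491601 to 4541560, with 99 on chromosome 1, 1096 on chromosome 3 and 824 on a separate sequence of the mating-type region. The genome build of these positions was not given in the sources used here. Gene identity, strand and position came from the deposited probe annotation, and a RefSeq gene table (assembly ASM294v3) supplied symbols and list membership for 899 of the 903 genes with probes.

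Scanner files of 3 arrays (∆mlo3, mlo3-A and mlo3-A ∆cid14) were used. Per the file headers they were written by Agilent Feature Extraction 10.1.1.1. The deposited spot and background signals are intensity values (scanner units, median over pixels). Processed signals in the same files are intensity values that the authors' software had corrected for background and dye, per the file headers. The log ratio per spot is on a log10 scale of Cy5 over Cy3 per the file headers. The p-value per spot comes from the software's error model in the deposited files. Deposited flags of other kinds (0 or 1) mark outlier, saturated and well-above-background spots. The authors also deposited a value table for all 4 arrays on a log2 scale, mutant over wild type. Against the scanner files, its nonzero values differed from the log ratio by at most 0.005, and values were set to 0 where the p-value was 0.05 or more, which held 46.7% of values for ∆mlo3, 71.6% for mlo3-A and 50.6% for mlo3-A ∆cid14. The mlo3-A ∆h2a.z column (61.6% zeros) was taken to follow the same rule, and all column medians were 0.

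Median spot signals were used because mean signals were missing from 1 array. Outlier spots were left out (1359 or 3.09% for ∆mlo3, 374 or 0.85% for mlo3-A, 1318 or 3.00% for mlo3-A ∆cid14), and no spot was saturated. Background was corrected by normexp with an offset of 50 and the log2 ratios were normalised within each array by loess in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table). Levels of single channels were compared after quantile scaling of average intensities. Summaries and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. For mlo3-A ∆h2a.z, and for its difference from mlo3-A, the deposited value table was used as it stands. Differences between mutants are differences of log2 ratios of the same probe.

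A gene's value was the median over its unique probes on the sense or the antisense strand of its coding region. Genes with at least 4 probes, at least 50% of them well above background in either channel, were assessed. A gene counted as higher or lower when its median log2 ratio was at least 1 from 0 and at least 75% of its probes lay on that side of 0. With 1 array per genotype no test was made, and these size limits take its place. For mlo3, whose mutant channel was not well above background in ∆mlo3, the fold is a lower bound from the lowest signal that was, and for other genes with a dim wild-type channel the fitted ratio is printed without a bound. The genes named were the deleted genes, then, among genes past 2-fold with at least 5 probes, the 8 highest and 8 lowest in sense and the 8 highest and 4 lowest in antisense signal, and up to 4 members of each list. This rule, the lists, the comparisons and the alternatives were fixed before the data were examined. A gene or feature outside the rule is said to be chosen after its value was seen.

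The lists were core stress genes, heat shock chaperones, meiotic mRNAs removed by Mmi1, genes named mug or meu, mating genes, RNAi and heterochromatin factors, RNA surveillance, exosome and export genes, histone and SWR1 genes, iron genes, phosphate genes, ribosomal protein genes, convergent and tandem genes, pseudogenes, subtelomeric and mating-type genes, and probe groups for non-coding RNAs, LTRs and Tf2 elements. Each list's median was placed among those of 10000 random lists matched on mean intensity in 10 bins, as a description only. Overlaps between arrays were set against the product of the shares and against 1000 simulations of unchanged arrays that share a wild type, with the spread of wild-type signal between the 3 scanned arrays (median SD 0.26 over 750 genes for sense, 0.14 over 755 for antisense). Features with repeated sequence (tlh genes, Tf2 elements, centromere, chromosome ends) were read from all of their probes and their copies were not separated.

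The steps were tested on simulated data built on the mlo3-A array, with 200 changed features and probe noise of 0.3 (SD, log2). Of sense changes of log2 1.5, 2 and 3, 94.1% (32 of 34), 100% (32) and 100% (32) were called. Of antisense changes, 39.3% (11 of 28), 69.7% (23 of 33) and 100% (28) were called, with median estimates of 0.96, 1.10 and 1.99, so antisense changes on the dimmest array were underestimated and partly missed. None of 643 unchanged sense and 536 unchanged antisense features was called. The simulated noise was independent between probes, with no spread shared by a gene's probes and no dye bias of single probes. It therefore gives no rate of false calls for the real arrays. Alternatives were no background correction, median centring in place of loess, a loess curve fitted on sense probes only, the software's processed signals, the value table, no detection requirement, only probes well above background in both channels, the mean over probes, at least 8 probes, and centring of the value table. The processed signals and the value table differ from the chosen steps in background and dye correction together.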

Results

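RNA abundance was measured in fission yeast (Schizosaccharomyces pombe) with 4 tiling arrays, each read in 2 colours. On every array, Cy5-labelled total RNA from 1 mutant strain was hybridised beside Cy3-labelled wild-type RNA. The mutants were ∆mlo3, which lacks the gene for the RNA-binding protein Mlo3, mlo3-A, an altered form of that gene that the labels do not explain, and the double mutants mlo3-A ∆cid14 and mlo3-A ∆h2a.z. Cid14 is a nuclear poly(A) polymerase of RNA surveillance, and H2A.Z is a histone variant encoded by pht1. Cells grew in rich medium at 30 °C. Each genotype had 1 array and no dye swap, so there was no replicate check and the number of arrays limits the precision. Any dye bias stays in the ratios to wild type. The spread given with each gene (±) is the SD over its probes, and genes described as highest or lowest, or as rising or falling most, are so among genes with at least 5 probes. The probes read both strands of part of chromosome 2 and short pieces of the other chromosomes, and covered 903 genes. Median signal was 174 (Cy3) and 406 (Cy5) units for ∆mlo3, 155 and 185 for mlo3-A, and 224.5 and 804 for mlo3-A ∆cid14, over a background of 23, 24 and 23 units in Cy3 and 57, 53 and 60 in Cy5. At least 98.8% of sense probes were well above background in either channel of these arrays, while antisense probes ranged from 50.8% (Cy3, ∆mlo3) to 93.3% (Cy5, mlo3-A ∆cid14). Signals of the mlo3-A ∆h2a.z array were known only as log2 ratios in the deposited value table.

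The deleted genes were read first, as a check of the labels. The 5 sense probes of mlo3 (SPBC1D7.04, chromosome 2, 1746011 to 1746470, minus strand) had a log2 ratio of −8.01 ± 0.55 on the ∆mlo3 array, at least 187-fold lower than in wild type. The same probes stood at −0.43 ± 0.14 in mlo3-A, 0.23 ± 0.13 in mlo3-A ∆cid14 and 0.00 in mlo3-A ∆h2a.z. pht1 (SPBC11B10.10c, chromosome 2, 1503611 to 1503970) fell in mlo3-A ∆h2a.z, with a log2 ratio of −7.11 ± 0.73 over 4 probes, and stood at −0.13 in ∆mlo3, 0.21 in mlo3-A and 0.46 in mlo3-A ∆cid14. No probe covered cid14, so this deletion could not be read. Antisense signal over mlo3 was 3.36 ± 0.22 in mlo3-A ∆cid14, 1.17 ± 0.12 in mlo3-A and −0.30 in ∆mlo3 by loess. In the value table it was 3.47 in mlo3-A ∆cid14, 3.17 in mlo3-A, 2.52 in mlo3-A ∆h2a.z and 0.00 in ∆mlo3, and the difference of mlo3-A ∆h2a.z from mlo3-A was −0.70 ± 0.37. The rise of 2.35 by loess from mlo3-A to mlo3-A ∆cid14 shrank to 0.72 in the value table, below 2-fold.

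**Figure D1:**
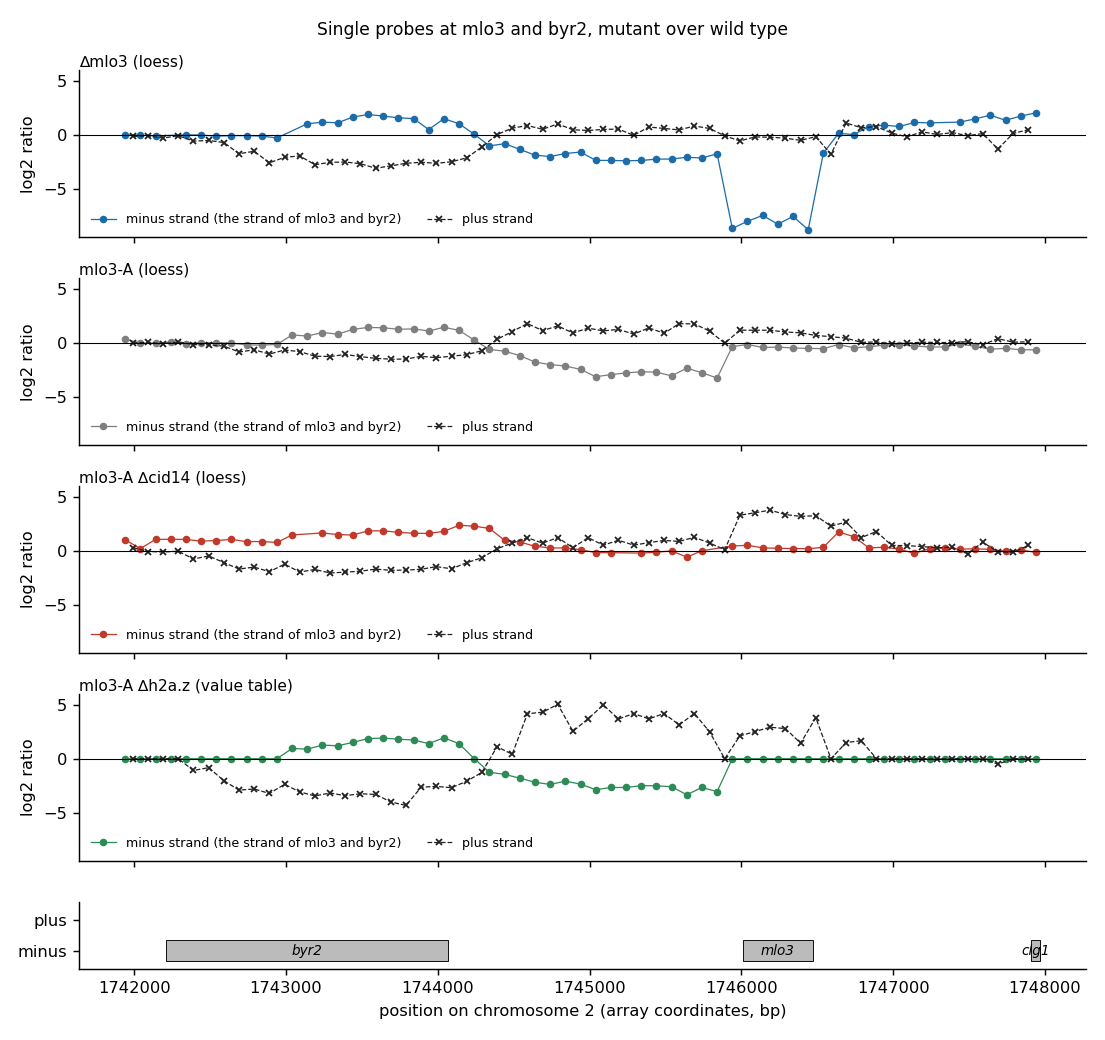
Log2 ratios of mutant to wild type for single probes around mlo3 on chromosome 2 (position in bp on the array), with the strand of mlo3 and byr2 and the opposite strand in separate colours and 1 panel per array. The sense probes of mlo3 have a median of −8.01 on the ∆mlo3 panel and medians between −0.43 and 0.23 on the others.

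The comparison of ∆mlo3 with wild type asked which sense and antisense RNAs depend on Mlo3. Antisense signal was higher by at least 2-fold over 73 of 599 assessed genes and lower over 13. Large rises in antisense signal were over SPBC1711.09c, a SNARE-associated Golgi protein (2.92 ± 0.25), the GRIP domain gene grp2 (2.73 ± 0.31), nvj2 (2.65 ± 0.47), crr1 (2.58 ± 0.28), the DNAJ gene spf31 (2.41 ± 0.21) and the kinase gene gsk31 (2.20 ± 0.39). ish1, which faces the 3' end of grp2 at 291 bp, had higher sense signal (2.46) on this array. Wild-type signal was not well above background for 21 of the 73 genes, among them the nickel transporter gene nic1 and the kinesin gene klp5. Their fitted ratios of 2.58 and 2.27 therefore have no settled place among the others, ranging from 2.31 and 2.02 under a loess curve fitted on sense probes alone to 4.27 and 3.73 with processed signals. Antisense signal fell over the gene next to mlo3, byr2 (−2.51 ± 0.99), over the nuclear rim gene amo1 (−1.77 ± 0.25) and over the pseudogenes SPCC1884.01 (−1.77 ± 0.91) and SPCP20C8.03 (−1.35 ± 0.43). The median antisense ratio of all assessed genes was 0.19, and moved to 0.49 with processed signals and to −0.19 with the sense-probe curve. Under the sense-probe curve 43 genes had higher and 31 lower antisense signal.

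Sense signal in ∆mlo3 was higher by at least 2-fold for 72 of 740 genes and lower for 47. Among genes with at least 5 probes, the highest were lsd90 (3.21 ± 0.41 over 17 probes), SPCC757.02c (2.89 ± 0.44, with wild-type signal not well above background), the phosphoketolase gene SPBC24C6.09c (2.78 ± 0.22) and knh4 (2.59 ± 0.25). The place of SPCC757.02c is not settled, as its ratio ranged from 2.61 under the sense-probe curve to 4.63 with processed signals. but2, of the neddylation pathway, rose by 2.53 ± 0.17, the spermine-family transporter gene SPBC409.08 by 2.47 ± 0.13, SPBC725.03 by 2.46 ± 0.06 and the nuclear envelope gene ish1 by 2.46 ± 0.30. Besides mlo3, the lowest of these were the tRNA dihydrouridine synthase gene dus2 (−2.03 ± 0.10), gem8 (−1.88 ± 0.20), the DNA repair gene swi10 (−1.73 ± 0.07) and the kinetochore gene sim4 (−1.53 ± 0.09). eri1, which encodes a ribonuclease for double-stranded siRNA, fell by 1.53 ± 0.04, zng1 by 1.52 ± 0.10 and the HMG box gene SPBC19G7.04 by 1.51 ± 0.10. The split of higher to lower genes depended on the scaling, at 130 to 33 under median centring (all-gene median 0.17) and 50 to 59 under the sense-probe curve (−0.16), and at 57 to 19 among genes with at least 8 probes.

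The comparison of mlo3-A with wild type asked what the altered gene does where mlo3 is still expressed. Sense signal was higher for 3 of 741 genes, the enolase gene eno101 (1.37 ± 0.26, but 0.42 in the value table), the small heat shock gene hsp16 (2.40 ± 0.10) and the ribosomal protein gene rpl1102 (1.07 ± 0.11). It was lower for 4, the siderophore-iron transporter gene str1 (−1.68 ± 0.38), the oligopeptide transporter gene isp4 (−1.17 ± 0.32), SPBP23A10.11c (−1.12 ± 0.22) and the ubiquitin hydrolase gene ubp11 (−1.09 ± 0.11). Antisense signal was higher over 3 of 625 genes, nvj2 (1.39 ± 0.41, and 3.16 in the value table), mlo3 itself and SPBC146.02 (1.03 ± 0.13). It was lower over 5, namely SPCC1884.01 (−1.64 ± 0.67), the mannosyltransferase gene alg2 (−1.42 ± 0.38), the FAD transporter gene flx1 (−1.08 ± 0.18), byr2 (−1.04 ± 0.53) and, named after its value was seen, SPBC14C8.11c (−1.14). These splits turned with the scaling. Sense signal gave 20 higher and 2 lower genes under median centring (all-gene median 0.39), 3 and 2 under the sense-probe curve, 2 and 10 with processed signals and 3 and 9 in the value table. Antisense signal gave 8 and 3 under median centring and 7 and 2 under the sense-probe curve (all-gene median 0.12), and the value table had 22 higher and 29 lower genes.

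**Figure D2:**
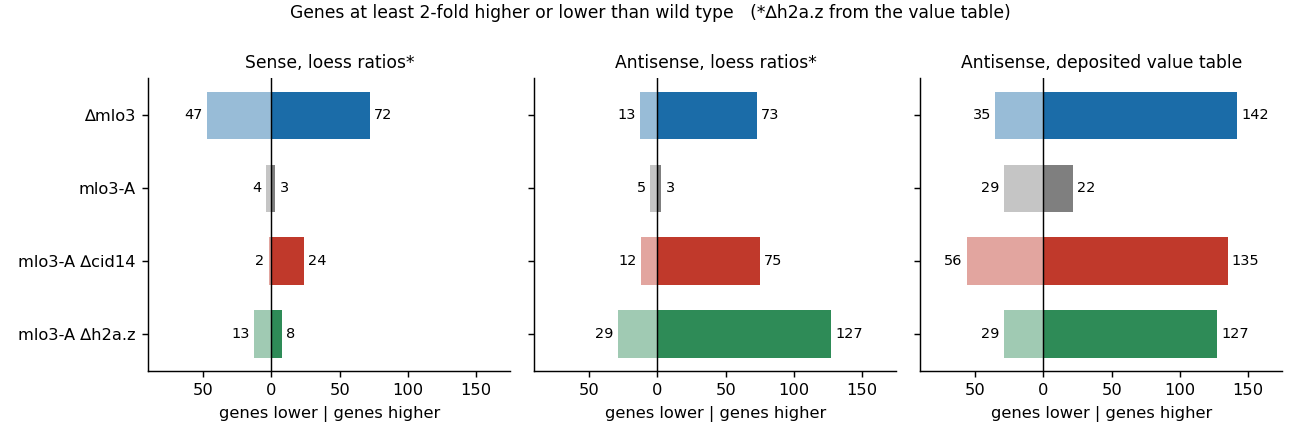
Number of genes (x axis) with signal at least 2-fold higher (bars to the right) or lower (bars to the left) than in wild type, by array (y axis), for sense signal, antisense signal and antisense signal from the deposited value table. In the value table, higher antisense signal covered 142 genes in ∆mlo3, 22 in mlo3-A, 135 in mlo3-A ∆cid14 and 127 in mlo3-A ∆h2a.z.

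The double mutant mlo3-A ∆cid14 addressed the part of Cid14 when mlo3 is altered. On the strand of mlo3 past its coding region this array stood at 0.00 where mlo3-A stood at −2.68, and with neither the mlo3 allele nor the cid14 deletion of this strain readable, its differences from mlo3-A cannot be assigned to cid14 alone. Against wild type, antisense signal was higher over 75 of 733 genes and lower over 12. It was highest over the elongator subunit gene elp5 (3.57 ± 0.17), the securin gene cut2 (3.37 ± 0.22), mlo3, the replication origin gene orc2 (3.34 ± 0.40), the kinase gene ppk27 (3.07 ± 0.48), nvj2 (3.02 ± 0.42), the adenylate cyclase gene cyr1 (2.80 ± 0.40 over 51 probes) and grp2 (2.77 ± 0.28). Antisense signal fell over byr2 (−1.70 ± 0.63), the autophagy gene atg2402 (−1.35 ± 0.27), the TFIIIC gene sfc3 (−1.26 ± 0.52) and hpz1 (−1.19 ± 0.42). Sense signal was higher for 24 of 740 genes, led among those with at least 5 probes by lsd90 (4.91 ± 0.18), the invertase gene inv1 on chromosome 3 (3.85 ± 0.23), ish1 (2.41 ± 0.36), the protease gene rbd3 (1.85 ± 0.22), the transcription factor gene atf21 (1.82 ± 0.28), hsp3101 (1.77 ± 0.08), dbl7 (1.48 ± 0.14) and SPBC409.08 (1.48 ± 0.18). The M-factor transporter gene mam1 (−1.12 ± 0.17) and SPBC19G7.04 (−1.02 ± 0.14) were the 2 lower genes. The all-gene antisense median of 0.06 moved to 0.30 under median centring (142 higher to 1 lower), to −0.15 under the sense-probe curve (83 to 50) and to 0.13 with processed signals (159 to 70), and the value table split 135 to 56. The sense split was 24 to 11 under median centring (all-gene median −0.32) and 26 to 9 in the value table.

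Set directly against the mlo3-A array, where dye bias common to both arrays cancels, mlo3-A ∆cid14 had higher antisense signal over 71 of 741 genes and lower over 14. cut2 (3.45 ± 0.24), orc2 (3.32 ± 0.45), ppk27 (3.06 ± 0.60), elp5 (2.89 ± 0.19) and cyr1 (2.77 ± 0.44) were again among the highest, with the COMPASS subunit gene swd2 (2.75 ± 0.81), the ribonuclease gene tri1 (2.67 ± 0.60) and the arrestin gene art1 (2.48 ± 0.42). The lowest were atg2402 (−2.17 ± 0.54), tdh1 (−1.72 ± 0.41), SPBC146.02 (−1.48 ± 0.24) and SPBC1709.16c (−1.22 ± 0.21). Of 736 genes, 38 had higher and 5 lower sense signal. lsd90 (5.17 ± 0.25), inv1 (3.88 ± 0.25), ish1 (2.36 ± 0.34), the transcription factor gene gsf1 (1.91 ± 0.18), knh4 (1.90 ± 0.42), atf21 (1.81 ± 0.25), rbd3 (1.80 ± 0.31) and the WD repeat gene SPBC18H10.05 (1.78 ± 0.12) rose most, and chs2 (−1.08 ± 0.18), gem8 (−1.05 ± 0.10), hpz1 (−1.03 ± 0.06), aha1 (−1.02 ± 0.06) and rpl1102 (−1.11 ± 0.18) fell. The sense split turned to 22 higher and 164 lower genes under median centring, which moved the all-gene median to −0.69. The antisense split was 164 to 9 under median centring (all-gene median 0.37), 65 to 104 under the sense-probe curve (−0.28), 153 to 84 with processed signals (0.11) and 128 to 57 in the value table.

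The double mutant mlo3-A ∆h2a.z addressed the part of H2A.Z in the same setting, and all of its values came from the deposited table. Antisense signal was higher than in wild type over 127 of 744 genes, assessed by their signal on the other arrays, and lower over 29. nvj2 (4.08 ± 1.02), the SWI/SNF subunit gene sol1 (3.90 ± 1.55), the phosphatase gene siw14 (3.69 ± 0.82), the Arf GAP gene cnt5 (3.39 ± 1.31), the small G protein gene gtr1 (3.34 ± 1.03), crr1 (3.29 ± 0.26), klp5 (3.11 ± 0.65) and SPBC18H10.05 (2.94 ± 0.59) rose most in antisense signal. It fell over pht1 (−5.48 ± 3.59), byr2 (−2.91 ± 1.24), meu18 (−2.64 ± 0.31) and the G protein gene git5 (−2.34 ± 0.39). Sense signal was higher for 8 of 750 genes, among them the meiotic cyclin gene rem1 (2.49 ± 0.96), the thiamine gene nmt1 (1.28 ± 0.48), the meiotic recombination gene rec15 (1.21 ± 0.08), tdh1 (1.14 ± 0.31), the chaperone gene hsp78 (1.03 ± 0.07) and chs2 (1.01 ± 0.14). The 13 lower genes included pht1, str1 (−1.94 ± 0.58), the PWWP domain gene pdp1 (−1.78 ± 0.24), coa1 (−1.39 ± 0.07), isp4 (−1.30 ± 0.60), bot1 (−1.21 ± 0.09), rix7 (−1.14 ± 0.08), ubp11 (−1.12 ± 0.12) and SPBC18H10.05 (−1.08 ± 0.13).

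Against mlo3-A, mlo3-A ∆h2a.z had higher antisense signal over 126 of 744 genes and lower over 25, with sol1 (3.64 ± 1.64), gtr1 (3.34), crr1 (3.21 ± 0.34), the phosphatidylserine decarboxylase gene psd1 (3.10 ± 0.54), alg2 (3.06 ± 0.56), klp5 (2.99 ± 0.93), exo5 (2.95 ± 0.95) and SPBC18H10.05 (2.91 ± 0.58) highest. pht1 (−6.67 ± 3.98), meu18 (−2.67 ± 0.25), atg2402 (−2.32 ± 0.43) and SPBC146.02 (−2.25 ± 0.17) were lowest. The 8 genes with higher sense signal among 746 were rem1 (2.49), rec15 (2.39 ± 0.32), SPBC557.02c (1.38 ± 0.19), nmt1 (1.23 ± 0.53), the kinase genes ppk31 (1.15 ± 0.41) and pat1 (1.08 ± 0.26), the transcription factor gene scr1 (1.02 ± 0.29) and SPBC21D10.08c (1.02 ± 0.35). The 8 lower genes included pht1, pdp1 (−1.78), coa1 (−1.39), bot1 (−1.21), rix7 (−1.14), the endonuclease gene apn2 (−1.13 ± 0.24) and gpi3 (−1.06 ± 0.26). Of the deposited mlo3-A values, 71.6% were set to 0, and at those probes the difference only repeats the ratio to wild type. The medians of gtr1 antisense and of rem1, pht1, pdp1, coa1, bot1 and rix7 sense signal were the same in both comparisons, while that of rec15 was not. The counts against mlo3-A are therefore not separate from those against wild type.

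Loss of mlo3 was also set against its altered form. Antisense signal in ∆mlo3 exceeded that in mlo3-A by at least 2-fold over 81 of 684 genes and was lower over 16. It was highest over SPBC1711.09c (2.69 ± 0.24), crr1 (2.66 ± 0.21), nic1 (2.56 ± 0.25), the mitochondrial reductase gene rip1 (2.48 ± 0.19), grp2 (2.39 ± 0.40), gsk31 (2.19 ± 0.37), klp5 (2.18 ± 0.32) and spf31 (2.10 ± 0.11), and lowest over SPBC146.02 (−2.02 ± 0.16), atg2402 (−1.58 ± 0.56), the recombination gene sfr1 (−1.38 ± 0.14) and mlo3 (−1.38 ± 0.17). The places of nic1 and klp5 are not settled here either, as wild-type signal on the ∆mlo3 array was not well above background. Sense signal was higher for 98 of 738 genes and lower for 72. knh4 (3.65 ± 0.48), lsd90 (3.59 ± 0.43), but2 (3.43 ± 0.33), scr1 (3.0 ± 0.30), SPCC757.02c (2.91 ± 0.54, its place not settled for the same reason), the cyclin gene clg1 (2.84 ± 0.24), SPBC24C6.09c (2.82 ± 0.23) and pib2 (2.78 ± 0.41) rose most. Of these, clg1 lies next to mlo3 and scr1 next to clg1, and a local effect of the change at mlo3 was not tested. After mlo3 (a fitted −7.86, with signal in ∆mlo3 not well above background), gem8 (−2.05 ± 0.14), swi10 (−1.79 ± 0.11), zng1 (−1.67 ± 0.11), the SAGA gene sgf29 (−1.65 ± 0.13), SPBC17A3.08 (−1.62 ± 0.14), pmt1 (−1.57 ± 0.10) and dus2 (−1.52 ± 0.09) were lowest. The antisense split turned to 35 higher and 89 lower under the sense-probe curve (all-gene median −0.42), and was 190 to 73 with processed signals (0.28). The sense split was 105 to 127 under median centring (−0.23) and 73 to 103 under the sense-probe curve (−0.22), and 81 to 22 among genes with at least 8 probes.

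Higher antisense signal recurred over the same genes for some pairs of arrays. Of 596 genes assessed in both, 31 had higher antisense signal in ∆mlo3 (73 genes) and in mlo3-A ∆cid14 (71 genes), where independent calls would share 8.70 and simulated unchanged arrays with the same wild-type RNA shared 2.08. In the value table, ∆mlo3 (142) and mlo3-A ∆h2a.z (121) shared 67 of 599 genes, against 28.7 and 2.13. mlo3-A ∆cid14 (135) and mlo3-A ∆h2a.z (126) shared 50 of 733, against 23.2 and 2.10, and mlo3-A (22) and mlo3-A ∆h2a.z (110) shared 11 of 625, against 3.87 and 2.13. By loess, mlo3-A had 2 higher genes in its pair with ∆mlo3 and shared 1, against 0.23 if independent. It had 3 in its pair with mlo3-A ∆cid14 and shared 2, against 0.32. These calls are too few to be set against the 2.03 of simulated arrays. Higher sense signal in ∆mlo3 (70) and mlo3-A ∆cid14 (23) was shared by 12 of 733 genes, against 2.20 and 7.89. In every other pair an array had at most 7 such genes, too few to reach the 7.72 to 8.10 of simulated arrays, so that comparison decides nothing. The most shared was 5, by ∆mlo3 and mlo3-A ∆h2a.z, where independent calls would share 0.73. The simulated antisense values stayed between 2.03 and 2.13 for every pair, whatever the number of genes called. They rest on the spread of the scanned arrays also where calls came from the value table. Arrays with many calls can exceed them for that reason alone, so they lend the shared counts no support. Part of each excess over independent calls may come from the wild type used on every array and cannot be split off.

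**Figure D3:**
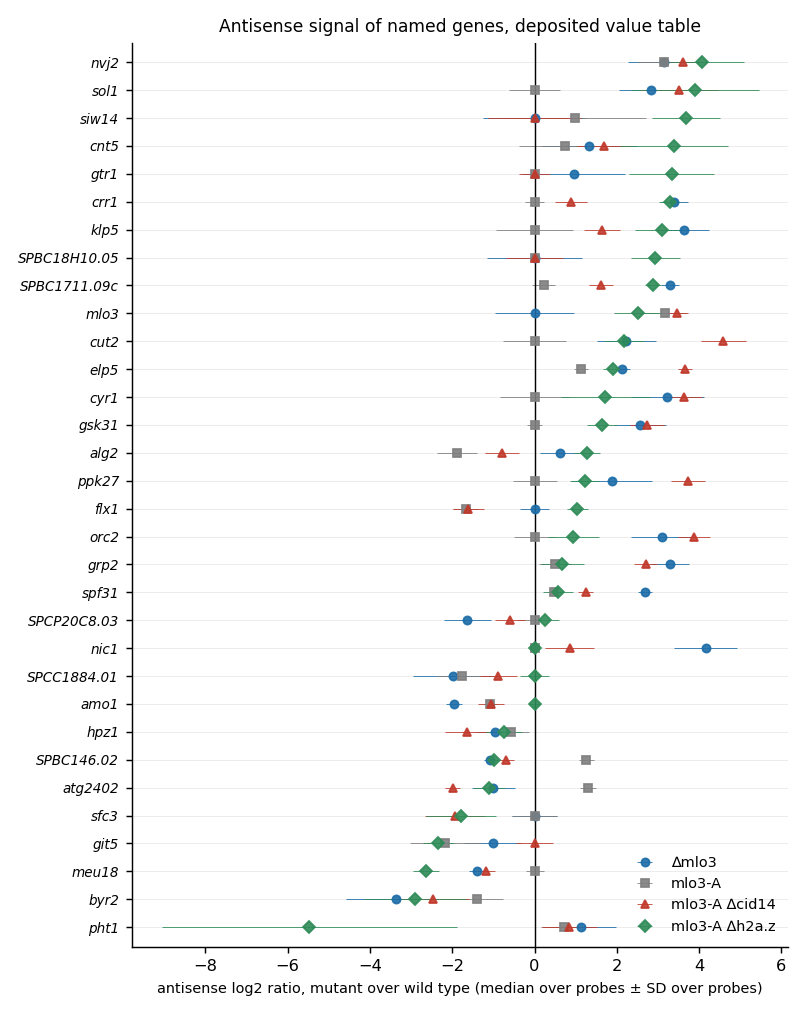
Antisense log2 ratio of mutant to wild type (x axis) for the named genes (y axis), 1 point per array with the SD over probes as the bar, all from the deposited value table. nvj2 reaches 4.08 in mlo3-A ∆h2a.z, and byr2 lies below 0 on all 4 arrays.

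Groups of genes fixed beforehand were read next, with each list's median set among random lists of like intensity. Of 18 core stress genes, 5 were on the array and 4 were assessed. All 4 rose in ∆mlo3, namely hsp16 (2.77), ish1 (2.46), the transcription factor gene atf1 (1.98) and the peroxidase gene gpx1 (1.57), for a median of 2.22 at percentile 99.99. In mlo3-A ∆cid14 hsp16 (3.87) and ish1 (2.41) rose, gpx1 stood at 0.87 and atf1 at 0.71, and the median was 1.64. In mlo3-A the median was 0.11 at percentile 77.6 and hsp16 was the 1 higher gene. In mlo3-A ∆h2a.z the median was 0.46, with hsp16 at 3.16 and gpx1 at 0.93. Relative to mlo3-A, hsp16 stood at 0.29 in ∆mlo3 and at 1.5 in mlo3-A ∆cid14. The list had positive medians under every scaling tried in both ∆mlo3 and mlo3-A ∆cid14.

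Of 13 meiotic mRNAs that the RNA-binding protein Mmi1 removes in growing cells, 3 were on the array and assessed. In mlo3-A ∆cid14 the transcription factor gene mei4 (1.37 ± 0.29) and spo5 (1.14 ± 0.19) rose, rec8 stood at 0.37, and the median of 1.14 lay at percentile 98.2. Against mlo3-A, spo5 (1.44) and mei4 (1.37) were higher and the percentile was 98.6. The median was 0.50 in ∆mlo3 (percentile 73.5), −0.11 in mlo3-A and 0.00 in mlo3-A ∆h2a.z, where antisense signal over rec8 was lower (−1.01). Among 12 genes named for upregulation in meiosis (mug and meu), 11 were assessed in ∆mlo3, where mug176 was higher (1.13) and mug124 lower (−2.51). Antisense signal rose over mug93 (1.53) and meu17 (1.39) in ∆mlo3 and over the same genes in mlo3-A ∆cid14 (2.25 and 1.23), and fell over meu18 in ∆mlo3 (−1.06). In mlo3-A ∆h2a.z it was lower over meu18 and mug20 (−1.46) and higher over mug57 (1.0).

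Of 31 mating genes, 7 were on the array and 5 assessed. The adhesin gene map4 was higher in ∆mlo3 (1.14) and lower in mlo3-A ∆h2a.z (−1.01). In mlo3-A ∆cid14 byr2 was higher (1.46) and mam1 lower, and the list median of 0.63 lay at percentile 96.4. byr2 lies next to mlo3, and its signal was uneven along the gene in every mutant. Antisense signal over rep1 rose in mlo3-A ∆h2a.z (1.58). Of 24 RNAi and heterochromatin factors only clr1 and tas3 were assessed and neither passed 2-fold in sense signal, while antisense signal over clr1 rose in ∆mlo3 (1.80 ± 0.25) and mlo3-A ∆h2a.z (2.39 ± 0.45), and stood at 0.06 in mlo3-A and 0.38 in mlo3-A ∆cid14. Of 26 RNA surveillance, exosome and export genes, 3 were on the array and mlo3 and mex67 were assessed, with mex67 between −0.15 and 0.10. Of 21 histone and SWR1 genes, 5 were on the array and pht1 and rvb2 were assessed, with rvb2 at −0.58 in ∆mlo3, −0.08 in mlo3-A, −0.24 in mlo3-A ∆cid14 and 0.00 in mlo3-A ∆h2a.z. The iron list had 11 genes with 2 on the array. str1 was lower in ∆mlo3 (−1.28), mlo3-A and mlo3-A ∆h2a.z, stood at −0.50 in mlo3-A ∆cid14, and was 1.12 higher there than in mlo3-A, while antisense signal over php4 rose in mlo3-A ∆h2a.z (1.53 ± 0.22). Of 8 phosphate genes pho7 alone was covered, and was higher in ∆mlo3 (1.11). Of 12 heat shock chaperone genes mas5 alone was covered, at 0.45 in ∆mlo3, −0.18 in mlo3-A, −0.26 in mlo3-A ∆cid14 and 0.00 in mlo3-A ∆h2a.z.

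Of 26 ribosomal protein genes on the array, 13 were assessed in ∆mlo3, where rpl2502 was lower (−1.09) and the median of −0.35 lay at percentile 31.8. In mlo3-A, 12 were assessed with a median of 0.32 at percentile 99.99, which turned to −0.31 with processed signals. The median was 0.02 in mlo3-A ∆cid14 (12 genes, percentile 95.2, none past 2-fold) and 0.00 in mlo3-A ∆h2a.z (13 genes, none past 2-fold). Genes whose downstream neighbour lies on the opposite strand (486 convergent genes) were compared with 385 tandem genes for antisense signal. In ∆mlo3 it was higher over 55 and lower over 4 of 371 convergent genes, and higher over 17 and lower over 7 of 218 tandem genes, with medians of 0.31 and −0.03. The convergent median turned to −0.04 under the sense-probe curve, where the all-gene median was −0.19. In mlo3-A ∆cid14 the counts were 57 and 5 of 419 convergent genes and 18 and 7 of 304 tandem genes, with medians of 0.16 and −0.04, the latter turning to 0.18 under median centring. In mlo3-A ∆h2a.z they were 100 and 12 of 424, and 26 and 15 of 310, from the value table and so not on the scale of the other arrays. In mlo3-A they were 2 and 4 of 355, and 1 and 0 of 261. Sense signal was higher and lower for 37 and 25 convergent and 32 and 21 tandem genes in ∆mlo3, 2 and 3 against 1 and 1 in mlo3-A, 13 and 2 against 8 and 0 in mlo3-A ∆cid14, and 2 and 8 against 5 and 5 in mlo3-A ∆h2a.z. Of 11 pseudogenes, SPCP20C8.03 was assessed and its sense signal was higher in mlo3-A ∆cid14 (1.04 ± 1.05). None of the 31 subtelomeric genes of chromosome 2 and neither of the 2 mating-type genes had enough unique probes to be assessed.

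Probes that match repeated sequence or lie outside protein-coding genes were read as groups. The sense strand of the Tf2 retrotransposons rose in ∆mlo3 (2.04 ± 0.27, all 69 probes at least 2-fold higher), and stood at −0.98 ± 0.48 in mlo3-A, 0.31 ± 0.11 in mlo3-A ∆cid14 and 0.00 in mlo3-A ∆h2a.z. Against mlo3-A it was higher by 2.93 in ∆mlo3, 1.30 in mlo3-A ∆cid14 and 1.02 in mlo3-A ∆h2a.z, the value for mlo3-A ∆cid14 moving to 0.57 under median centring. The telomere-linked RecQ helicase genes tlh1 and tlh2, read with probes that match several copies and chosen after their values were seen, had sense ratios of −2.65 ± 0.30 in ∆mlo3, −1.87 ± 0.41 in mlo3-A, 1.76 ± 0.44 in mlo3-A ∆cid14 and 0.47 ± 0.25 in mlo3-A ∆h2a.z. Against mlo3-A, they stood at 3.79 ± 0.75 in mlo3-A ∆cid14, 2.57 ± 0.69 in mlo3-A ∆h2a.z (value table) and −0.73 ± 0.55 in ∆mlo3. Intron probes (56, sense strand) stood at −0.96 ± 0.74 in ∆mlo3, where 46.4% were at least 2-fold lower, and at 0.22 in mlo3-A, 0.02 in mlo3-A ∆cid14 and 0.00 in mlo3-A ∆h2a.z. Probes for tRNA (4) stood at −0.01, 3.48, 2.62 and 1.58 in ∆mlo3, mlo3-A, mlo3-A ∆cid14 and mlo3-A ∆h2a.z, and those for 5S rRNA (6) at 0.38, 2.45, 1.70 and 0.58, the values for mlo3-A ∆h2a.z being from the value table. In ∆mlo3 the 5S rRNA value turned to −0.50 and the tRNA value moved to −1.11 with processed signals, and in the value table they were −0.60 and −1.21. In mlo3-A the tRNA value ranged from 2.55 with processed signals to 4.23 under median centring, and the 5S rRNA value from 1.61 to 3.31. In the same order, medians were −0.62, −0.07, −0.26 and 0.00 for snRNA (6 probes), −0.10, 0.29, 0.25 and 0.00 for snoRNA (4), −0.23, −0.05, 0.13 and 0.00 for other non-coding RNA (60), and 0.18, −0.17, 0.21 and 0.00 for LTRs (26). Of these LTR probes 34.6% were at least 2-fold higher in mlo3-A ∆cid14. Some signs turned with the scaling, LTRs to −0.28 in ∆mlo3 and −0.06 in mlo3-A ∆cid14 and other non-coding RNA to 0.02 in mlo3-A under the sense-probe curve, and snRNA to 0.07 in mlo3-A and 0.09 in mlo3-A ∆cid14 and snoRNA to 0.13 in ∆mlo3 under median centring.

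The right end of chromosome 2 (4491601 to 4541560, 16.9% of probes unique) had a median of 0.54 in mlo3-A ∆cid14, with 34.1% of probes at least 2-fold higher and 1.11% lower, and medians of −0.09 in ∆mlo3, 0.05 in mlo3-A (−0.15 under median centring) and 0.00 in mlo3-A ∆h2a.z. Over the scalings the median in mlo3-A ∆cid14 ranged from 0.43 under the sense-probe curve to 1.29 with processed signals. Across centromere 2 (1597561 to 1650020) the median was −0.41 in ∆mlo3, with 25.7% of probes at least 2-fold lower and 2.05% higher, and −0.99 with processed signals. The centromere stood at 0.02 in mlo3-A (−0.17 under median centring), 0.01 in mlo3-A ∆cid14 (14.8% higher, 3.22% lower, median −0.51 under the sense-probe curve) and 0.00 in mlo3-A ∆h2a.z (2.82% higher, 32.1% lower). The separate sequence of the mating-type region had medians of −0.07, 0.01, −0.10 and 0.00 in ∆mlo3, mlo3-A, mlo3-A ∆cid14 and mlo3-A ∆h2a.z. Under the sense-probe curve its median was −0.72 in ∆mlo3 and −0.62 in mlo3-A ∆cid14, and under median centring −0.21 in mlo3-A.

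**Figure D4:**
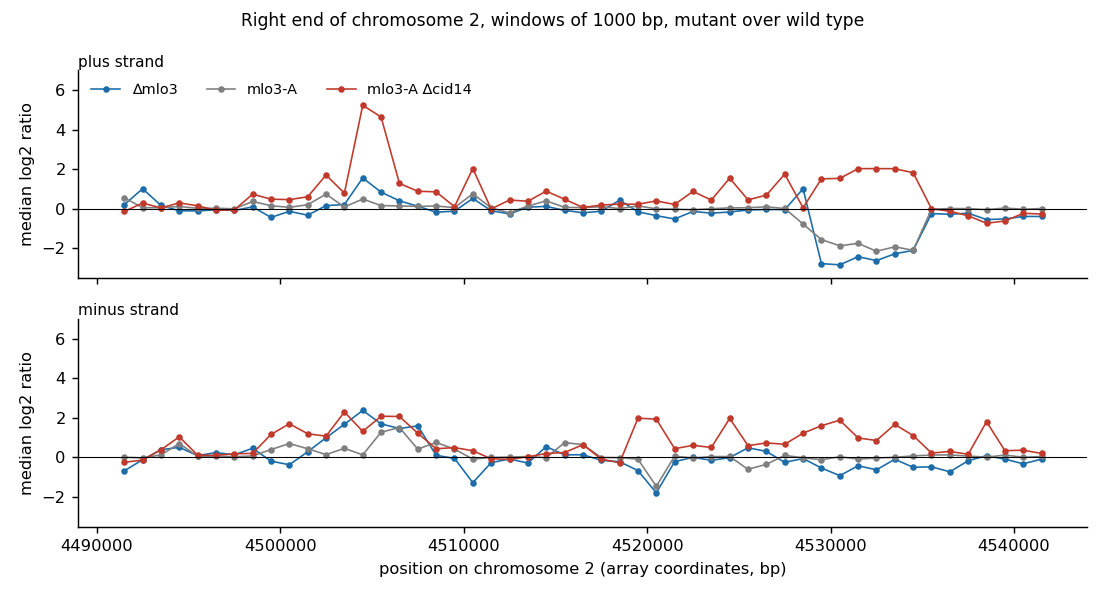
Median log2 ratio of mutant to wild type (y axis) in 1000-bp windows along the right end of chromosome 2 (x axis, position on the array), by strand, for the 3 arrays with scanner signals. The mlo3-A ∆cid14 line lies mostly above 0 (region median 0.54), and the ∆mlo3 and mlo3-A lines drop below 0 on the plus strand over the tlh genes near the end.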

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

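The tests of dye bias over antisense probes, of ribosomal protein mRNAs and all 3 tests at the mlo3 locus were chosen after the results were seen.

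Some genes passed 2-fold in opposite directions in different mutants, and the differences between the groups were not tested. The gap between the highest and lowest passing log2 ratios was 2.97 for isp4 sense signal (1.67 in ∆mlo3, −1.17 in mlo3-A, −1.30 in mlo3-A ∆h2a.z), 2.24 for SPBP23A10.11c (1.12 in ∆mlo3, −1.12 in mlo3-A), 2.15 for map4 (1.14 in ∆mlo3, −1.01 in mlo3-A ∆h2a.z) and 2.39 for SPBC18H10.05 (1.31 in mlo3-A ∆cid14, −1.08 in mlo3-A ∆h2a.z). For antisense signal it was 3.06 for rsv1 (1.08 in mlo3-A ∆cid14, −1.98 in mlo3-A ∆h2a.z), 2.70 for alg2 (−1.42 in mlo3-A, 1.28 in mlo3-A ∆h2a.z), 2.33 for duo1 (−1.01 in ∆mlo3, 1.32 in mlo3-A ∆h2a.z), 2.27 for mis13 (1.02 in mlo3-A ∆cid14, −1.25 in mlo3-A ∆h2a.z) and 2.15 for flx1 (−1.11 in mlo3-A ∆cid14, 1.05 in mlo3-A ∆h2a.z). Values for mlo3-A ∆h2a.z came from the value table and the others from the loess ratios.

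Signal also appeared outside annotated features, which the comparisons of genes do not use. Stretches of at least 5 consecutive unique probes at least 2-fold higher than wild type numbered 57 in ∆mlo3, 0 in mlo3-A, 56 in mlo3-A ∆cid14 and 49 in mlo3-A ∆h2a.z. The number for mlo3-A ∆h2a.z came from the value table and the others from loess ratios, so it is not on their scale. Between these scales the genes with higher antisense signal in mlo3-A went from 3 to 22. In ∆mlo3 they included 17 probes between klp9 and gsf1 (2.16 ± 0.24, SD over probes), 15 between clg1 and scr1 (2.03) and 13 between SPBC31A8.02 and but2 (2.42), all on the plus strand. These examples were chosen after their values were seen. but2 and scr1 were themselves named above for higher sense signal, scr1 in ∆mlo3 against mlo3-A. Whether the stretches next to them belong to the RNAs of these genes was not tested.

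Antisense signal was higher over many genes in ∆mlo3 (73 genes, median 1.39) and in mlo3-A ∆cid14 (75 genes, median 1.47). Copies of the sense strand made during labelling, if made alike in the mutant and wild-type reactions, would need higher sense signal of the same genes. Their median sense ratios were −0.08 and −0.14. More copying in the mutant reaction could raise antisense ratios alone, so these values do not settle this cause. A fixed dye bias would recur on the mlo3-A array, where the same genes had median antisense ratios of 0.05 and 0.06, although simulated antisense changes were underestimated on that array. With processed signals these ratios were 0.23 and 0.18. A dye bias that varies with signal need not recur there and was not tested. Median antisense Cy5 signal was 96 on that array, against 192 in ∆mlo3 and 333 in mlo3-A ∆cid14. Transcription past the end of a convergent neighbour cannot be told apart from independent antisense RNA, since the probes between the genes had medians of 0.05 in ∆mlo3 and 0.62 in mlo3-A ∆cid14 (SD 0.81 over genes on each) against −0.14 and −0.07 at genes without higher antisense signal, and the neighbour had higher sense signal for 6 of 41 and 8 of 47 genes against 22 of 282 and 4 of 319. Among the pairs with a higher neighbour, grp2 faced ish1 at 291 bp (sense 2.46 in ∆mlo3 and 2.41 in mlo3-A ∆cid14). Likewise swd2 faced SPBC18H10.05 at 291 bp (sense 1.31 in mlo3-A ∆cid14). The loss of mlo3 and of cid14 stay open as biological causes and were not tested, as each strain has 1 array.

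All 4 assessed core stress genes were higher in ∆mlo3 (median 2.22), and 2 of the 4 in mlo3-A ∆cid14 (median 1.64, SD 1.48 over genes). A low wild-type level on these arrays would give the same ratios, but the wild-type channel was higher than on the mlo3-A array, by 0.72 and 1.15. The wild-type level of these genes thus differed between arrays (SD 0.54 and 0.68 over genes), for a cause that was not tested. Normalisation is argued against by the lowest list medians over the other scalings, which stood 2.20 and 1.63 above all genes. A general stress response with lower ribosomal protein mRNAs is argued against in mlo3-A ∆cid14, where their median lay at percentile 95.2. In ∆mlo3 it cannot be told apart from a narrower change, since the percentile was 31.8 against wild type but 0.69 against mlo3-A, whose own ribosomal protein median changed sign with the scaling, and culture differences between strains were not tested.

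On the strand of mlo3, median signal past its coding region (1744511 to 1745970) was lower in ∆mlo3 (−2.14), mlo3-A (−2.68) and mlo3-A ∆h2a.z (−2.51) but stood at 0.00 in mlo3-A ∆cid14, while the probe next to the coding region (1745911 to 1745970) read like the coding ones, at −8.67, −0.35, 0.00 and 0.44. Dye bias common to the arrays cancels between them and is argued against by the difference of 2.47 between mlo3-A ∆cid14 and mlo3-A (SD 0.60 over probes). A lower level of the whole mlo3 mRNA is argued against by the coding probes, at −0.43 in mlo3-A. A change in the DNA past that probe may be present in some strains, since the median of the 3 probes at 1745711 to 1745970, that probe included, lay 2.35 below the coding ones in mlo3-A. This is a hypothesis from the same data, an earlier end of the mRNA was not tested against it, and the labels do not describe the alleles.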

How the results depend on the processing

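All alternatives were chosen before the data were examined. Counts are of genes past 2-fold (sense) or at least 2-fold higher (antisense), and the cause of each change was not tested. Under median centring, antisense counts went from 73 to 113 in ∆mlo3, 3 to 8 in mlo3-A, 75 to 142 in mlo3-A ∆cid14 and 71 to 164 in mlo3-A ∆cid14 against mlo3-A, and sense counts from 7 to 22 in mlo3-A and 43 to 186 in mlo3-A ∆cid14 against mlo3-A. With the sense-probe curve, antisense counts were 43 in ∆mlo3, 7 in mlo3-A and 35 (from 81) in ∆mlo3 against mlo3-A. Processed signals gave antisense counts of 200 in ∆mlo3, 24 in mlo3-A, 159 in mlo3-A ∆cid14, 153 in mlo3-A ∆cid14 against mlo3-A and 190 in ∆mlo3 against mlo3-A, and sense counts of 12 in mlo3-A and 40 (from 26) in mlo3-A ∆cid14. The value table gave antisense counts of 142, 22, 135, 128 and 143 in the same order and a sense count of 12 in mlo3-A. Without background correction the antisense count of mlo3-A was 6. With at least 8 probes, which leaves fewer genes, sense counts were 76 (from 119) in ∆mlo3 and 103 (from 170) in ∆mlo3 against mlo3-A. Some list medians changed sign. The ribosomal protein median of mlo3-A was −0.31 with processed signals. With the sense-probe curve the antisense median of convergent genes was −0.044 in ∆mlo3 (all genes −0.19), −0.091 in mlo3-A ∆cid14 against mlo3-A (all genes −0.28) and −0.21 in ∆mlo3 against mlo3-A (all genes −0.42), and with median centring that of tandem genes was 0.18 in mlo3-A ∆cid14 (all genes 0.30) and 0.22 against mlo3-A (all genes 0.37). The other 37 antisense and 48 sense counts stayed within 1.5 times, 178 list medians moved by less than the spread over genes and 26 by more. Of the values of named genes, run under median centring, processed signals and the value table only, 213 moved by more and 174 by less than the SD over probes. None of those past 2-fold turned to the opposite sign, while values that became 0 and values not past 2-fold were left out of that check. Centring moved nothing for mlo3-A ∆h2a.z, whose column median was 0. The list of genes with introns was not run, as the array annotation gives no exons per gene. Low signal over background limits the antisense values, with 50.8% (Cy3) of antisense probes well above background in ∆mlo3 and 61.9% (Cy5) in mlo3-A.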

Other observations

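No test in this part was planned, and its values were chosen after they were seen. Along the gene byr2, which lies past mlo3 on the same strand, the array read uneven signal in every mutant. In the part of byr2 nearer mlo3 (1743211 to 1744070) sense log2 ratios were 1.51 in ∆mlo3, 1.26 in mlo3-A, 1.65 in mlo3-A ∆cid14 and 1.73 in mlo3-A ∆h2a.z, while in the farther part they were −0.07, −0.02, 0.95 and 0.00. Antisense ratios in the nearer part were −2.64, −1.28, −1.79 and −3.31. On the strand opposite mlo3, past its coding region, ratios were 0.53 in ∆mlo3, 1.19 in mlo3-A, 0.81 in mlo3-A ∆cid14 and 3.94 in mlo3-A ∆h2a.z.

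Near the left end of chromosome 3 (1 to 49970), probes at least 2-fold higher made up 41.0% of the minus strand in ∆mlo3, 38.4% in mlo3-A, 40.6% in mlo3-A ∆cid14 and 12.4% in mlo3-A ∆h2a.z, and 0.82%, 9.09%, 9.45% and 11.2% of the plus strand, with 33.8% of all these probes unique. That end was read from all of its probes. Among unannotated probes of chromosome 2, all unique and over both strands together, these shares were 6.76%, 0.70%, 7.39% and 8.55%. The sets of probes are unlike, so their shares are not directly comparable. Shares for mlo3-A ∆h2a.z came from the value table. Antisense probes of snRNA genes stood at 1.44 ± 1.16 in mlo3-A ∆cid14. Over the 3' UTR probes, sense medians were −0.11 in ∆mlo3, −0.04 in mlo3-A and −0.10 in mlo3-A ∆cid14, and over the 5' UTR probes −0.16, −0.12 and −0.31. Under median centring they were 0.02, 0.35 and −0.39 over the 3' UTR and 0.19, 0.19 and −0.59 over the 5' UTR. Stretches outside annotated features with at least 5 consecutive probes 2-fold lower numbered 43 in ∆mlo3, 11 in mlo3-A, 14 in mlo3-A ∆cid14 and 63 in mlo3-A ∆h2a.z. The last number came from the value table and is not on the scale of the others.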
